A study of Mus musculus with 116 samples.

How the data were processed

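RNA was measured in mouse oocytes and embryos. The 5 total RNA libraries, each from about 100 oocytes or embryos, covered MII oocytes, PN5 zygotes, early 2-cell embryos, and late 2-cell embryos of a control group and of a group labelled mTBE. The abbreviation is not expanded in the labels and is used here as a name. Per the labels' protocols these libraries were made from total RNA depleted of ribosomal RNA. The other 2 libraries came from the inner cell mass (ICM) and were made with Smart-seq2, which selects polyadenylated RNA. The other 109 samples of the series were not analysed here.

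The authors deposited FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for each gene symbol. The submitters' processing notes name CASAVA 1.8, TopHat2 2.1.1, Cufflinks 2.1.1 and genome build mm9, without a role for each file. How multi-mapped reads were assigned and whether strand was used are not given in the sources used here. Genes that share reads with a near-identical copy, that overlap or that lie antisense to each other are therefore uncertain. PN5 and both late 2-cell libraries share a table, the ICM libraries share a second table, and MII and early 2-cell each had a table of their own. The MII and early 2-cell values carry 6 decimals and the others 6 significant digits, so the tables may have been written by different steps. No value was rescaled between tables in the main calculation. Levels set side by side across these tables were normalized separately. No value column lacked a sample (0 columns). The single value column of the MII table bears a name that a chromatin sample of the series also bears; the table is listed with the MII total RNA sample, and the column was taken as that library on this ground.

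The tables held 24029 to 24578 rows. Rows that shared a symbol, 497 in the 3-library table and 495 in each single-library table, were summed. The 24028 symbols present in all tables were used for comparisons that span tables. Gene symbols were taken as the files give them. A RefSeq table of assembly GRCm38, which differs from the authors' build, served only to find which symbols have a named pseudogene, and no coordinate was taken from it.

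The difference between 2 libraries was calculated per gene on the log2(FPKM + 1) scale, with a pseudocount of 1 FPKM, which understates the fold of low genes. A gene entered a comparison at 1 FPKM or more in at least 1 of the 2 libraries. It was counted as higher or lower at a difference of at least 1 on that scale, about 2-fold. Each group of the 5 total RNA libraries held 1 library, so no p-value or standard error could be calculated and no difference between these groups has a replicate check. Read depth is unknown for the total RNA libraries: ratios of low values between late 2-cell libraries showed no steps, with at most 14 of 600 genes at the same ratio. In the ICM libraries 282 of 1972 genes below 0.3 FPKM lay at 1 ratio, which places replicate 1 at about 2.11 times the depth of replicate 2.

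Gene lists, 23 in all, were written down with the comparisons, the size rule, the onset classes, the alternative settings and the rule for naming genes before the data were examined. They cover 2-cell genes, the Obox family, genome activation factors, ribosome biogenesis, ribosomal proteins, translation factors, proteasome, RNA polymerase II machinery, splicing, oocyte maternal genes, pluripotency, trophectoderm, primitive endoderm, cumulus and granulosa cells, sperm, replication histones, p53 targets, heat shock, immediate early genes, cell cycle, DNA methylation, oxidative phosphorylation and snoRNA host genes. For each list the median difference was placed among the medians of 10000 random lists of the same size, drawn from genes outside the list and matched on mean level in 20 bins. A list was said to stand apart when its median lay outside the central 95% of those lists. The percentile describes these libraries and is not a test of the condition. The 23 lists were examined in 7 comparisons, the ICM pair included; a list with fewer than 3 measured genes was given no percentile, which left 22 lists for early 2-cell against PN5 and 21 for the ICM pair.

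Genes were named by 1 rule. For each comparison these were the 10 largest increases and 10 largest decreases among genes at 10 FPKM or more in at least 1 library, and from each list up to 4 measured members with the highest mean level. For mTBE against control the 10 largest in each direction were all small noncoding RNAs. The 10 largest of each comparison were therefore also listed without small RNA symbols, a choice made after seeing the data. Any other gene named is said to have been chosen after its values were seen. Onset classes placed each gene by the first stage at which it was at least 4-fold above MII on the log2(FPKM + 1) scale, using the mean of both late 2-cell libraries for the last stage.

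The 3 planned steps between successive stages each set 2 separately made tables side by side. After seeing the data, 2 comparisons within 1 kind of table were added: late 2-cell control against PN5, and early 2-cell against MII. The alternatives tried were a pseudocount of 0.1, no filter, and a filter of 5 FPKM. Further ones were scaling to a median log2 ratio of 0 over genes at 5 FPKM or more in both libraries, and values rescaled to a sum of 1000000. The last was the highest row in place of the sum for repeated symbols. For the onset classes a threshold of 2-fold in place of 4-fold, and a late level from the control or the mTBE library alone, were tried as well. The counts of ICM genes were also taken without either replicate.

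The size rule and the list percentile were tested on simulated data for mTBE against control, with 14018 genes in the step and a spread taken from the ICM replicates. The genes set to change were drawn only from those at 10 FPKM or more in control, so recovery of lower genes was not tested. In the real comparison, 107 of 765 higher and 843 of 1371 lower genes were at 10 FPKM or more in at least 1 library. Of 50 genes set 2 log2 units higher and 50 set 2 lower, 50 and 50 were recovered. Of 50 set 1.5 higher 45 were recovered, and of 50 set 1.5 lower 46. Of 13818 genes left alone, 848 also passed the size rule. Of 23 lists without change 1 stood apart. The simulated noise was independent between genes, so this does not tell how often lists stand apart between real libraries. Between the ICM replicates 12 of 21 lists did. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9.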

Results

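The series studied RNA polymerase II and gene activation in mouse oocytes and preimplantation embryos. The RNA libraries analysed here were 1 of MII oocytes (mature oocytes, taken 13 h after hCG, the hormone that triggers ovulation), 1 of zygotes at PN5, the late pronuclear stage (30 h), 1 of early 2-cell embryos (36 h), 2 of late 2-cell embryos and 2 of the inner cell mass (ICM) of blastocysts (98 h). The late 2-cell embryos came from zygotes collected 23 h after hCG. They were kept for 14 h in 0.1% DMSO (control) or in 60 uM DRB, an inhibitor of transcription elongation by RNA polymerase II (the group labelled mTBE), then released and cultured for 12 h. Values were the authors' FPKM. They were at 1 FPKM or more for 10130 genes in MII, 9997 in PN5, 9511 in the early 2-cell, 12472 in the control, 13022 in the mTBE, and 9638 and 9396 in the ICM libraries.

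The comparison of mTBE with control late 2-cell embryos asked how expression stood after a temporary block of transcription. Genes with a transient peak at the 2-cell stage were lower in the mTBE library. Of 39 measured, 21 were at least 2-fold lower, 0 were at least 2-fold higher, and the median difference in log2(FPKM + 1) was -1.07, below each of 10000 matched random lists. Tmem92 was at 74.3 FPKM in control and 23.9 in mTBE embryos, Gm13078 at 69.6 and 19.9, and B020004J07Rik at 58.0 and 25.2. Zfp352, a marker of the 2-cell stage, lay within 2-fold at 95.7 and 70.3 FPKM. The homeobox genes Obox3 (88.7 and 26.7 FPKM) and Obox6 (72.1 and 29.8) were also lower, whereas Obox5 (414 and 604) and Obox1 (85.8 and 108) were not. The median of the 4 measured Obox genes was -0.46, at percentile 2.11, and it no longer stood apart with a filter of 5 FPKM. Family members of both lists share near-identical sequence and are uncertain one by one.

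Genes of ribosome biogenesis, which encode nucleolar and ribosome assembly factors, were the next lowest list. Of 88 measured, 38 were at least 2-fold lower in the mTBE library and 1 was higher, with a median of -0.88, again below each matched list. Rrp9, a U3 snoRNP protein, was at 84.5 FPKM in control and 20.6 in mTBE embryos, and Imp3 at 79.9 and 24.4. Rrn3, an initiation factor of RNA polymerase I, was at 79.4 and 48.3 FPKM, and its subunit Polr1d at 61.3 and 45.6. Ribosomal protein genes followed with a median of -0.61 over 64 genes, of which 17 were at least 2-fold lower and 8 higher. This list also stood apart between the 2 ICM replicates, with a median of -0.31. Rpl41 was at 297 and 149 FPKM and Rps9 at 87.2 and 34.8. Many ribosomal protein genes have pseudogene copies, and single members of this list are uncertain. Of its 79 genes 58 were at 1 FPKM or more in control and 53 in mTBE embryos, against 78 in the separately normalized MII library. The list as a whole is therefore uncertain as well.

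Other lists of general cell machinery had lower medians in mTBE embryos as well, each outside the central 95% of matched lists. These were splicing (-0.55, 45 genes), the proteasome (-0.53, 40), translation factors (-0.47, 48), cell cycle (-0.44, 36), oxidative phosphorylation (-0.40, 60), RNA polymerase II machinery (-0.37, 74), genome activation factors (-0.34, 28) and replication histones (-0.18, 59). Between the 2 ICM replicates, cell cycle (-0.39), splicing (-0.31), RNA polymerase II machinery (-0.29) and oxidative phosphorylation (-0.07) also stood below matched lists. Replication histones (0.55) stood above. The sign depends only on which replicate is subtracted. These lists therefore differ between replicates too. In most of them the members were within 2-fold: 7 of 45 splicing genes, 10 of 40 proteasome genes, 12 of 48 translation factors and 7 of 36 cell cycle genes were at least 2-fold lower, with 0 higher. Their most abundant members often did not follow the median. Over all genes with a mean of 100 FPKM or more the median was 0.20, so this is not particular to these lists. Psme3 of the proteasome was at 216 FPKM in control and 321 in mTBE embryos, Eif1 at 137 and 202, and Max at 114 and 203. Ccne1, encoding cyclin E1, was at 141 and 62.6 FPKM, Srsf1, a splicing factor, at 86.6 and 55.2, and the histone gene Hist1h1a at 4252 and 5103.

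Oocyte maternal, trophectoderm and primitive endoderm genes did not have lower medians. Of 65 oocyte maternal genes 0 were at least 2-fold lower and 1 was higher, with a median of 0.14 at percentile 95.5. Tcl1 was at 1545 FPKM in control and 2500 in mTBE embryos, Btg4 at 1529 and 1948, and Omt2b at 1438 and 1868. Trophectoderm genes had a median of 0.25 over 20 genes (percentile 99), with Gata2, a trophectoderm transcription factor, at 13.3 and 26.7 FPKM, Id2 at 12.5 and 17.9, Tfap2c at 29.0 and 30.1, and Krt18 lower at 15.6 and 11.4. snoRNA host genes had a median of 0.38 over 13 genes (percentile 99.6), although Snhg1 was lower, at 38.0 and 16.3 FPKM. Primitive endoderm genes had a median of 0.34 over 16 genes (percentile 97.4). Their sign turned with a filter of 5 FPKM, to -0.05.

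The remaining lists did not stand apart. Their medians were -0.22 for 19 heat shock genes, -0.21 for 14 genes of DNA methylation, -0.12 for 25 p53 targets, -0.11 for 22 pluripotency genes and 0.12 for 20 immediate early genes. Within them, Hspa5, a chaperone of the endoplasmic reticulum, was at 173 FPKM in control and 88.1 in mTBE embryos, Dppa5a at 59.0 and 21.5, Sall4 at 85.0 and 43.3, and Mdm2 at 90.0 and 58.1. Pou5f1 was at 203 and 236 FPKM and Dppa3 at 355 and 437. Markers of other cell types were measured for a minority of genes. Cumulus and granulosa genes had a median of 0.22 over 9 measured of 20, with Serpine2 at 49.5 and 57.7 FPKM and Amhr2 at 16.7 and 2.12. Sperm transcripts had a median of 0.30 over 7 measured of 15, with Odf2 at 81.7 and 101 FPKM and Tnp1 at 1.92 and 4.98.

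**Figure D1:**
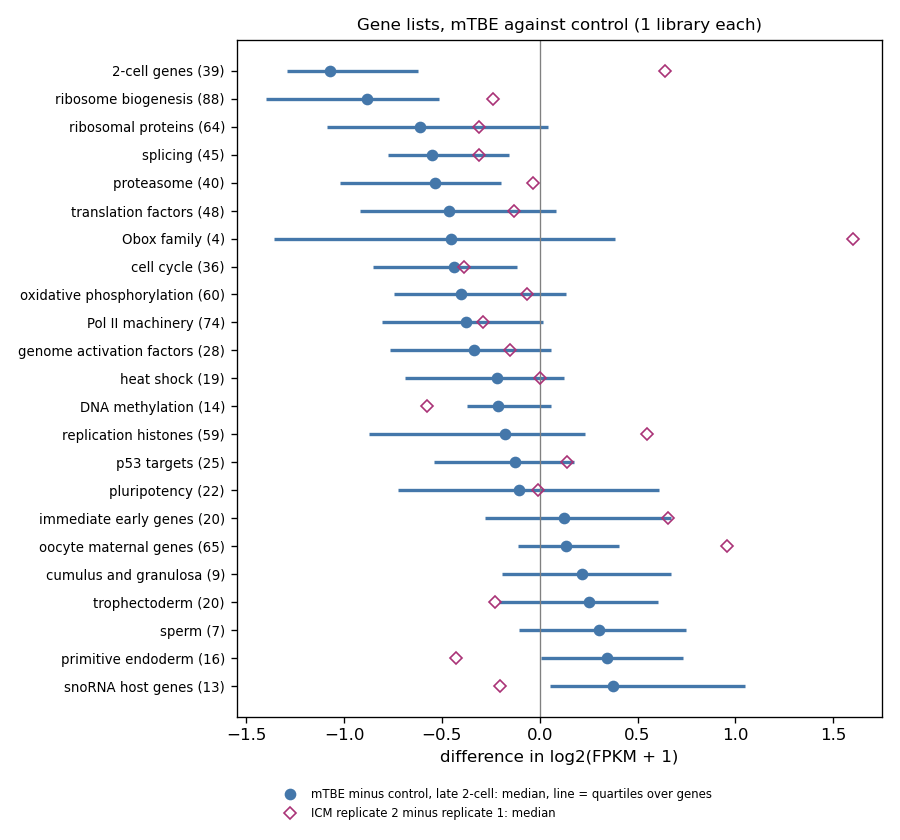
Median difference in log2(FPKM + 1) between the mTBE and the control late 2-cell library for each gene list (filled circles, with a line from the lower to the upper quartile over genes, and the number of measured genes in parentheses), beside the difference between the 2 ICM replicates for lists with at least 3 measured genes (open diamonds). The 2-cell genes (-1.07) and ribosome biogenesis (-0.88) have the lowest medians. The ICM replicates differ by 0.64 and -0.24 for these lists, and by -0.39 for cell cycle, where mTBE and control differ by -0.44. The sign of a replicate difference depends only on which replicate is subtracted. The 2-cell genes also stand apart from matched lists between the ICM replicates.

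**Figure D2:**
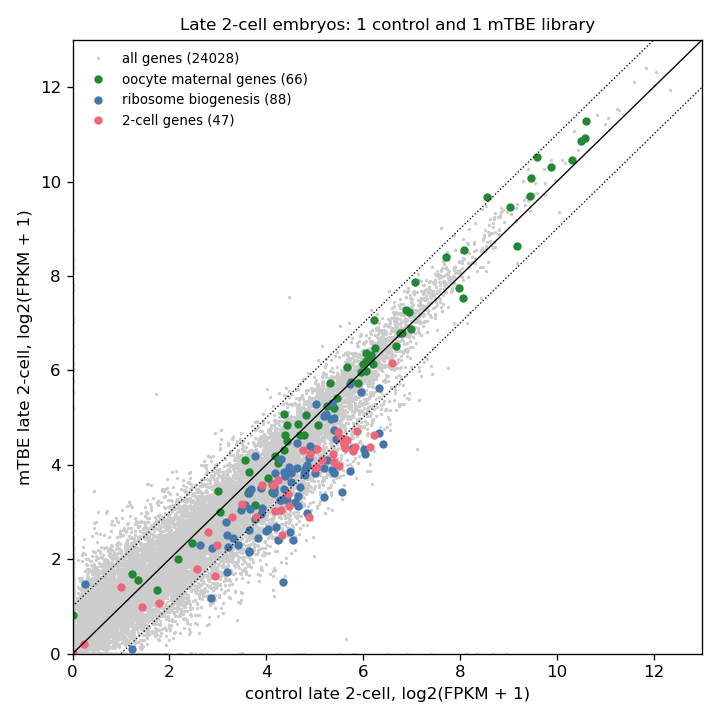
Level of each gene in the control (horizontal axis) and mTBE (vertical axis) late 2-cell library, as log2(FPKM + 1), for all 24028 genes and 3 gene lists. The solid line marks equal levels and the dotted lines a difference of 1; of the measured 2-cell genes 21 and of the ribosome biogenesis genes 38 lie on or below the lower dotted line, and 0 oocyte maternal genes do.

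Over all 13726 genes measured in this comparison, 765 were higher and 1371 lower in the mTBE library by the size rule. The 10 largest differences in each direction were all small noncoding RNAs listed at 0 in 1 library. Among them Scarna2 (497 FPKM) and Snord100 (327) were listed at 0 in mTBE embryos, and Snora68 (501) and Rnu11 (225) at 0 in control embryos. A list without small RNA symbols, chosen after seeing the data, held among its lower genes the alkaline phosphatase gene Alppl2 (138 FPKM in control and 19.3 in mTBE embryos), Stmn3 (30.8 and 3.21), Usp22 (19.8 and 2.13), Apom (16.9 and 1.35) and Tbl3 (19.4 and 1.87), whose product is a ribosome assembly factor. Its higher genes included Tshz1 (7.34 and 25.6 FPKM), Marcks (3.17 and 13.5), Tmem182 (6.66 and 24.4) and Hint1 (3.38 and 13.6). Amd1 (49.3 and 0.233 FPKM) and Amd2 (2.31 and 44.2), near-identical copies that are uncertain one by one, went in opposite directions.

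These differences have no replicate check. The 2 ICM libraries, made with another protocol, differed by the same size rule at 231 higher and 279 lower of 9983 genes. Between them 12 of 21 lists stood apart, against 14 of 23 for mTBE against control. Lists thus stood apart about as often between replicates, and standing apart does not by itself mark an effect of the treatment. The largest absolute list median was 1.6 between the replicates (4 Obox genes) and 1.07 for mTBE against control. The median difference also moved with the level of a gene, from 0.08 below a mean of 5 FPKM to -0.22 from 5 to 20 FPKM, -0.09 from 20 to 100 FPKM and 0.20 above that. The count of higher genes was 245 with a filter of 5 FPKM, where higher genes made up 18.4% of all counted in place of 35.8%. That share was 43.5% with median scaling (907 higher and 1177 lower) and 42.5% with a pseudocount of 0.1.

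Genes were then grouped by the stage at which they first stood at least 4-fold above MII. The 43 genes gained by the early 2-cell stage had a median of -0.56 in mTBE against control embryos, below each matched list, with 12 at least 2-fold lower and 2 higher. The 1597 genes gained by the late 2-cell stage had a median of -0.39, with 365 at least 2-fold lower and 79 higher. With an onset threshold of 2-fold in place of 4-fold these medians were -0.36 and -0.12, still below each matched list. The 98 genes gained by PN5 had a median of 0.19 (percentile 100 after rounding). Genes lost by the late 2-cell stage had a median of -0.16 over 683 genes (percentile 0.18). Genes at 1 FPKM or more in MII that fell in none of these classes had a median of -0.05 over 8352 (percentile 100 after rounding). The class gained by the late 2-cell stage depends on the late libraries themselves: its median was -0.64 when its genes were chosen on the control library and 0.04 when chosen on the mTBE library. For genes lost by the late 2-cell stage these medians were -0.007 (percentile 98.2, above matched lists) and -0.38 (percentile 0). MII and early 2-cell values came from separately normalized tables. Within the table shared by PN5 and the late 2-cell libraries, 1375 genes at least 4-fold above PN5 had a median of -0.56 (-0.76 when chosen on the control and -0.12, no longer apart from matched lists, when chosen on the mTBE library) and 509 genes lost since PN5 had a median of -0.09 (0.15 and -0.27 by the same choices), a grouping added after seeing the data.

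The change from PN5 to the late 2-cell control was followed first, within 1 table, a comparison added after seeing the data. The control embryos had been kept for 14 h in 0.1% DMSO and cultured for 12 h. No such treatment is recorded for PN5, so stage cannot be told apart from vehicle and culture here. The 2-cell genes were higher at the late 2-cell stage: 36 of 39 were at least 2-fold higher and 2 lower, with a median of 4.32. Zfp352 was at 0.241 FPKM in PN5 and 95.7 in the late 2-cell control, and Tmem92 at 1.36 and 74.3. Arg2 (141 and 32.3) and Sp110 (111 and 26.0), members of the same list, were lower. Obox6 was listed at 0 and at 72.1 FPKM, and Obox3 was at 0.347 and 88.7, while Obox1 was at 381 and 85.8. Replication histones had a median of 1.91, with 53 of 60 at least 2-fold higher and Hist1h3f at 604 and 2037 FPKM. Of the 67 histone genes 40 were at 1 FPKM or more in PN5 and 59 in the control, against 63 in the separately normalized MII library. The size of the histone difference is therefore uncertain. Of the lineage lists, trophectoderm (2.31, 19 genes) and pluripotency (1.51, 20 genes) stood above matched lists and primitive endoderm (0.65, 17 genes, percentile 37.4, and -0.14 with a filter of 5 FPKM) did not, although abundant members such as Pou5f1 (189 and 203) and Tfap2c (32.2 and 29.0) hardly differed. Ribosomal proteins also stood above (1.00, 60 genes, 30 at least 2-fold higher and 2 lower), with Rpl41 at 48.0 and 297 FPKM. Of their 79 genes 38 were at 1 FPKM or more in PN5 and 58 in the control, against 78 in the separately normalized MII library. The list as a whole is therefore uncertain here, as are its single members. Ribosome biogenesis stood above too (0.30, 87 genes, 26 higher and 16 lower), although its abundant members Bms1 (196 and 13.9 FPKM) and Riok1 (259 and 36.8) were lower. Immediate early genes (1.84, 18 genes), snoRNA host genes (2.18, 11), p53 targets (1.19, 25) and genome activation factors (0.80, 28) stood above as well, the p53 targets not with a filter of 5 FPKM.

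Maternal genes were lower at the late 2-cell stage than at PN5. Of 66 oocyte maternal genes 41 were at least 2-fold lower and 3 higher, with a median of -1.46. Bcl2l10 was at 1806 FPKM in PN5 and 707 in the late 2-cell control, whereas Btg4 (1582 and 1529) and Oosp1 (1063 and 1280) were within 2-fold. Proteasome genes had a median of -0.71 over 39 genes, with Psma2 at 168 and 18.8 FPKM and Psma7 at 159 and 17.7. Oxidative phosphorylation had a median of -0.41 over 60 genes, which no longer stood apart with a filter of 5 FPKM. Among the largest differences outside the small RNAs were the metallothionein genes Mt1 and Mt2, listed at 0 in PN5 and at 142 and 233 FPKM in the late 2-cell control, and the phosphate transporter gene Slc34a2 at 0.496 and 216. Rgs2, a regulator of G protein signalling, was at 356 and 10.9 FPKM and Pabpn1l, which encodes a poly(A)-binding protein, at 129 and 7.73. Of 13022 genes measured, 3970 were higher and 2218 lower. The median log2 ratio of genes at 5 FPKM or more was -0.13, and with a filter of 5 FPKM 2331 were higher.

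Early 2-cell embryos were compared with MII oocytes, whose tables have the same number format but were normalized separately, as a second comparison added after seeing the data. Genes at 5 FPKM or more had a median log2 ratio of -0.57, so that 429 of 10675 genes were higher and 3075 lower, against 918 and 1597 once that median was set to 0 and 940 and 2265 with values rescaled to a sum of 1000000. The 2-cell genes were higher, with 32 of 35 at least 2-fold higher, 1 lower and a median of 1.86. Dux, a transcription factor that activates 2-cell genes, was at 0.105 FPKM in MII and 25.4 in the early 2-cell library. In the table shared by PN5 and the late 2-cell libraries it was at 2.24 in PN5 and 0.991 in the late 2-cell control. That table lists 54 genes below 1 FPKM that the MII and early 2-cell tables have at 10 FPKM or more. The fall of Dux after the early 2-cell stage therefore cannot be told apart from the change of table. Usp17lc was listed at 0 in MII and was at 10.6 FPKM in the early 2-cell library. Replication histones had a median of 1.38 over 65 genes, with Hist1h1a at 925 and 4419 FPKM and Hist1h4c at 321 and 1189.

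Several maternal transcripts were far lower in early 2-cell embryos than in MII oocytes. Mos, which encodes the kinase that holds the oocyte in metaphase, was at 173 FPKM in MII and 7.46 in the early 2-cell library, Plat at 642 and 32.8, Bub1b, a spindle checkpoint kinase, at 422 and 12.2, and Gdf9, an oocyte growth factor, at 1411 and 144. The 65 oocyte maternal genes had a median of -1.08, below the median log2 ratio of -0.57 of genes at 5 FPKM or more. Bcl2l10 was higher, at 905 and 1346 FPKM. Ribosomal proteins (-2.14, 78 genes), oxidative phosphorylation (-1.76, 64), the proteasome (-1.63, 37), heat shock (-1.19, 18) and ribosome biogenesis (-1.01, 83) also stood below matched lists. With the median log2 ratio set to 0 these lists were at -1.63, -1.30, -1.13, -0.63 and -0.49, and oocyte maternal genes at -0.52, still below matched lists. Hspa8, a constitutive chaperone, was at 166 and 9.21 FPKM. Immediate early genes had a median of 0.40 over 12 genes, which turned to -0.30 with a filter of 5 FPKM.

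**Figure D3:**
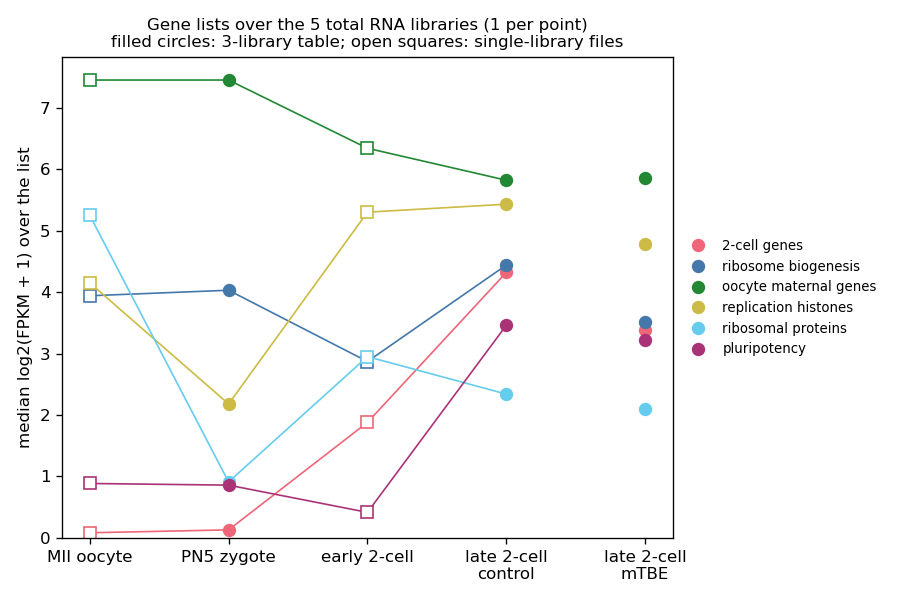
Median log2(FPKM + 1) of 6 gene lists in the 5 total RNA libraries, 1 library per point, over all members of each list. Filled circles come from the table shared by PN5 and late 2-cell embryos and open squares from the separately normalized MII and early 2-cell tables; the 2-cell genes stand at 0.08, 0.13, 1.88, 4.32 and 3.38 from left to right, and ribosomal proteins at 5.25, 0.91, 2.95 and 2.34 in the first 4 libraries.

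The 3 planned steps between successive stages each set separately normalized tables side by side. In the last step only the late 2-cell control had been kept in DMSO, so stage and treatment coincide. From MII to PN5 939 genes were higher and 989 lower of 10711, with a median log2 ratio of 0.33. With that log2 ratio set to 0, 345 were higher and 1309 lower. From PN5 to early 2-cell 732 were higher and 4243 lower of 10837, with a median log2 ratio of -0.86. Set to 0, it gave 1548 and 1730. From early 2-cell to late 2-cell control 6504 were higher and 1132 lower of 13126, with a median log2 ratio of 0.60. Set to 0, it gave 4359 and 1817. With values rescaled to a sum of 1000000, the 3 steps gave 558 higher and 1550 lower, 1545 and 2393, and 5317 and 2360. The 2-cell genes were higher in each step, with medians of 0.84 over 9 genes, 1.74 over 37 and 2.58 over 46, the first not apart from matched lists with a filter of 5 FPKM or without a filter. These medians were 0.66, 2.46 and 2.01 with the median log2 ratio set to 0 and 1.18, 3.39 and 2.14 with a sum of 1000000. The step with the highest median thus depends on the scaling. Ribosome biogenesis genes had a median of 1.57 over 88 genes in the last step, 57 of them at least 2-fold higher, and of 1.02 under either rescaling. Oocyte maternal genes had medians of 0.14, -1.15 and -0.12 in the 3 steps, but -0.19, -0.39 and -0.67 with the median log2 ratio set to 0. With a sum of 1000000 they were -0.16, -0.56 and -0.81, so which step had the lowest median depends on the scaling.

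Some large differences in these steps followed the kind of table. Hist2h2aa1 was at 1152 FPKM in MII, 1.63 in PN5 and 3052 in the early 2-cell library, and Akr1b3 at 222 in MII and 164 in the early 2-cell library but near 0 in PN5 and both late 2-cell libraries. Gapdh, a glycolytic enzyme gene that all cells use, named after its values were seen, was listed at 0 in PN5 and in the control, at 0.192 in the mTBE library, at 7.12 in MII and at 4.23 in the early 2-cell library. In all, 54 genes were below 1 FPKM in each library of the 3-library table yet at 10 FPKM or more in both MII and early 2-cell libraries, and 9 showed the reverse. Ribosomal proteins had medians of -3.58 over 78 genes, 1.40 over 73 and -0.20 over 78 in the 3 steps. These were -3.76, 2.13 and -0.67 with the median log2 ratio set to 0 and -4.68, 2.58 and -0.91 with a sum of 1000000. A gene listed at 0 in that table is not taken as absent.

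The ICM libraries were examined for the level of lineage genes and for the spread between replicates. Both pluripotency and trophectoderm genes were abundant in these libraries. The median level in log2(FPKM + 1), averaged over the replicates, was 4.46 for the 24 pluripotency genes, 5.01 for the 23 trophectoderm genes and 2.17 for the 18 primitive endoderm genes. These levels do not tell which cells of the preparation carried the transcripts, so trophectoderm transcripts are not assigned to ICM cells. Among pluripotency genes, Dppa5a was at 7521 ± 1111 FPKM (SD, n = 2), Spp1 at 248 ± 65.4, Pou5f1 at 221 ± 82.8 and Dppa2 at 137 ± 15.1. Among trophectoderm genes, Krt18 was at 1054 ± 87.8, Fabp3 at 928 ± 59.1, Id2 at 502 ± 87.0 and Krt8 at 386 ± 72.2 FPKM, and among primitive endoderm genes Dab2 was at 124 ± 7.33 and Gata6 at 28.3 ± 5.42. Dppa3 was at 1155 ± 153 FPKM, Pramel6 at 230 ± 11.3 and Npm1, a nucleolar protein gene, at 547 ± 58.1. Of the 66 oocyte maternal genes, 12 were at 1 FPKM or more in replicate 1 and 22 in replicate 2, with Khdc3 at 556 ± 134 and Ooep at 112 ± 5.60 FPKM. The 2 libraries correlated at r = 0.984 across 24029 genes on the log2 scale, and genes are not independent replicates. In their mean 9607 genes reached 1 FPKM.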

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

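Groups of 1 library set the main limit, since no alternative can stand in for a replicate, and the unknown depth of the total RNA libraries limits what can be said of low genes. No paired analysis was possible because the compared groups have 1 library each. Of 137 list medians recalculated for mTBE against control, 134 stayed on their side of the matched range, and 3 crossed its edge (primitive endoderm under 2 alternatives and Obox under 1). The count of genes lower in mTBE embryos stayed within 1.5 times of 1371 under each alternative, including the removal of small RNA symbols, which was chosen after seeing the data. The count of higher genes was 1432 with a pseudocount of 0.1, 1165 with sums of 1000000 and 245 with a filter of 5 FPKM, which tests fewer genes.

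With median scaling, PN5 against MII gave 345 higher genes, early 2-cell against PN5 1548 higher and 1730 lower, late 2-cell control against early 2-cell 1817 lower, and early 2-cell against MII 918 higher and 1597 lower. With sums of 1000000 the same comparisons gave 558 higher and 1550 lower, 1545 higher and 2393 lower, 2360 lower, and 940 higher. A filter of 5 FPKM left 333 higher genes for early 2-cell against PN5, 2331 for late 2-cell control against PN5 and 176 for early 2-cell against MII. Oocyte maternal genes in PN5 against MII turned to -0.19 with median scaling and -0.16 with sums of 1000000, and immediate early genes in early 2-cell against MII to -0.30 with a filter of 5 FPKM. Of 204 list medians recalculated for the stage comparisons, 199 stayed on their side of the matched range. Among them were those of the oocyte maternal genes in PN5 against MII, which changed sign only. Unlike for mTBE against control, only selected lists of each stage comparison were recalculated. Most of the selected lists stood apart in the main calculation, which by itself favours stability. The figure therefore does not describe all lists and is not comparable with that for mTBE against control.

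The class gained by the late 2-cell stage turned to 0.0375 when chosen on the mTBE library alone, which by construction favours genes high in that library. Genes at 1 FPKM or more in MII that were in no gained or lost class turned to 0.0348 with median scaling. Genes lost by the late 2-cell stage no longer stood apart with a filter of 5 FPKM (-0.22). They lay above matched lists (-0.00657) when chosen on the control library alone, which by construction favours genes low in that library. For the other changes the cause was not tested. ICM genes reaching the minimum numbered 6288 at 5 FPKM, and 9396 to 9638 with either replicate left out.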

Other observations

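Genes named here and the tests below were chosen after the values were seen. Several genes that were low in PN5 and abundant in the late 2-cell control were lower in the mTBE library, although a choice of genes high in the control by itself favours lower values in mTBE. Nop2, an rRNA methyltransferase, was at 1.46 FPKM in PN5, 46.2 in the control and 9.68 in the mTBE library, and Kdm5b, a histone H3K4 demethylase, was at 1.26, 107 and 37.2. The metallothionein gene Mt1 was listed at 0 in PN5 and was at 142 and 40.6 FPKM in the late libraries, Mt2 was listed at 0 and was at 233 and 128, Slc34a2 was at 0.496, 216 and 65.0, and Trim43b was listed at 0 and was at 106 and 51.2. Gata3, a trophectoderm transcription factor, went the other way, at 4.93 FPKM in PN5, 2.60 in the control and 10.2 in the mTBE library, as did the oocyte growth factor gene Bmp15 at 1393, 766 and 1466.

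The 2 ICM replicates differed in several named genes. The Y-linked genes Eif2s3y and Ddx3y were at 27.5 and 15.4 FPKM in replicate 1 and listed at 0 in replicate 2, as were Uty and Kdm5d (1.67 and 0.927 in replicate 1). The X-linked noncoding RNA Xist was at 14.0 and 24.2 FPKM in replicates 1 and 2, and its antisense partner Tsix at 6.13 and 45.3. The ribosomal RNA precursor Rn45s was listed at 0 in replicate 1 and at 18491 FPKM in replicate 2. Oocyte maternal genes were listed above 0 for 36 of 66 in replicate 1 and for 63 in replicate 2, although replicate 1 was the deeper library, and the heat shock gene Hspa1a was at 0.767 and 37.4 FPKM.

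Genes gained since PN5 were lower in the mTBE library, with a median of -0.56 over 1375 genes. A delay of the whole embryo that withheld the same share of losses and gains would also leave genes lost since PN5 higher, by about 0.50. Their median was -0.086 (95% bootstrap interval over 509 genes -0.13 to -0.04), and -0.002 with median scaling (-0.04 to 0.04). Genes are not independent. Chosen on the control library alone, which by itself favours higher values in mTBE, the median was 0.15 (0.12 to 0.20) where 0.66 would be needed. With median scaling that choice gave 0.24 (0.21 to 0.28) where 0.58 would be needed. These values argue against a delay of that kind as the whole cause, but not as a part of it. Losses and gains need not run in step. As deposited, early 2-cell against PN5 had 4243 lower and 732 higher genes, and late 2-cell control against early 2-cell 1132 and 6504. With median scaling these were 1730 and 1548, then 1817 and 4359. A delay after most of the loss could leave the lost genes little changed and stays open. If the choice of genes by their late level were the cause, the median would lie near 0 when both late libraries weigh equally, but with median scaling it was -0.47 (-0.52 to -0.43); chosen on the mTBE library alone, and without scaling, it was -0.12, within the range of matched lists. The block of transcription named by the design stays open and cannot be told apart from any other difference between these embryos, since there is 1 library per treatment.

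Hox genes, which pattern the body axis after implantation, were higher in the mTBE library, a family picked after its values were seen: without a filter 38 of 41 were above the control and 2 below, 12 of them at least 2-fold higher (median at percentile 100 of lists matched on level), with means of 1.39 FPKM in control and 3.20 in mTBE embryos, and of the 9 at 1 FPKM or more in control 8 were above it (median 0.57). Hoxd13 was at 5.32 and 14.9 FPKM, and Hoxb9 at 4.13 and 8.59. Diffuse background such as genomic DNA would give a like gain in silent genes, but 1449 olfactory and vomeronasal receptor genes gained 0.043 FPKM on average (0.024 to 0.065) against 1.81 for Hox genes, and a delay of the whole embryo would leave Hox genes between their means of 0.391 FPKM in PN5 and 1.39 in control, but they were above both (median difference to control 0.61 over all 41, 0.53 to 0.93), which speaks against it unless they peak between the stages sampled. Other developmental families (Lhx, Pax, Tbx, Nkx, Fox and others, 121 genes, no filter) had a median of 0.30 at percentile 100, so a wider change at developmental genes may be involved. GC content was not tested, no replicate exists, and clustered Hox genes are not independent, so this remains a hypothesis.

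The 3-library table listed 54 genes below 1 FPKM that the MII and early 2-cell tables both had at 10 FPKM or more. A candidate explanation is that reads shared with near-identical copies were treated differently between tables: 242 genes with a named pseudogene, ribosomal proteins left out, had a median of 0.23 in the 3-library table against the other tables, at percentile 0.01 of matched lists, where all 12614 genes had a median of 0.60. Of the 54 genes 8 encode ribosomal proteins and 16 are microRNA symbols, which this test does not cover. Ribosomal proteins with a named pseudogene had a median of -2.30 over 63 genes and those without -0.47 over 15. A true change between stages cannot be told apart from this for the 54 genes, because table and stage coincide, although they would have to be lost after MII, regained by the early 2-cell stage and lost again.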
